A study of Mus musculus with 24 samples.

How the data were processed

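Gene expression was measured by RNA sequencing in the duodenum of male Cyp27b1-null mice, in 24 libraries that fall into 4 groups of 6 by diet (normal or rescue) and injection (vehicle or 1,25-dihydroxyvitamin D3, written 1,25D). Per the labels' protocols, 8 µg of total RNA was treated with DNase, ribosomal RNA was removed with the RiboMinus kit, and directional libraries were made with the ScriptSeq kit. TopHat and the mouse genome build mm9 are named in the submitters' processing notes; versions, the program that quantified the genes and its annotation are not given in the sources used here. The authors deposited 1 table of RPKM values per library (reads scaled to feature length and library size), per the file headers, and these values were used as deposited. Because the mouse genome at hand was of another build, no coordinates are given, and genes are named by the symbols in the files.

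Each table held 30795 entries for 25410 symbols. For 3470 symbols several entries, 8855 in all, shared a symbol, and their RPKM values were summed, so isoforms were not told apart. Values at exactly 0 were kept: 448 symbols were listed at 0 in all 24 libraries, and 25 symbols appeared as calendar dates and were not repaired. Near-identical copies (Cyp3a11 and Cyp3a16, the amylases and trypsins, the defensins and the histones) can share reads, so the split between them is uncertain. The deposited values carry no read totals, so the absolute depth is unknown. Relative depth was estimated from the steps between low RPKM values, which are multiples of what 1 read is worth, over 1244 rarely detected entries; 80.4% of library pairs matched the joint estimate within 0.05 on the log2 scale. By this estimate the deepest library (normal vehicle replicate 6, where few pairs matched) held 2.77 times the reads of the shallowest (rescue 1,25D replicate 4).

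Tests were made with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with an intensity trend in the empirical Bayes step, for the 20006 genes with an RPKM of 0.5 or more in at least 6 of the 24 libraries. All 24 libraries entered 1 fit with 1 mean per group and 20 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 5 comparisons were 1,25D against vehicle on each diet, rescue against normal diet under each injection, and the difference between the effects of 1,25D on the 2 diets (the interaction). Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. Tests were two-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the tables and draw the figures.

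In 36 gene lists with 710 positions, 698 positions were found in the files and 652 passed the filter on low values. Lists were tested with camera (in limma, with a preset correlation between genes of 0.01) and, beside it, with the correlation estimated from the libraries, each adjusted over the 36 lists of a comparison; fry, which asks whether the genes of a list move to 1 side on balance and makes no comparison with other genes, was run too. The genes named in the text follow a rule: per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among named genes with a mean of 1 RPKM or more in the higher group; up to 4 members of each list with the smallest unadjusted p; and Cyp27b1, Cyp24a1, Vdr, Trpv6, S100g and Atp2b1 throughout. The text names a part of these genes, and that part was picked after the values were seen. Design, lists, naming rule and most alternatives were fixed before the data were examined.

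The mean log2(RPKM + 0.5) over a list in a library served as its score. A background score was taken over 1338 olfactory and vomeronasal receptor genes, which the duodenum is not known to use, and a score of 19 general epithelial genes was added; both were chosen after the data were seen. Scores, relative depth and summed RPKM were compared between groups with exact permutation tests over 924 splits, adjusted over 24 tests, and other single values with permutation tests of 100000 resamples. On simulated data for 1,25D on the normal diet, with 200 of 20006 genes changed, 61% of genes changed by log2 1 and 96% of those changed by log2 2 were called. Among the calls were 7 unchanged genes, and the median error of the fold change was 0.15. With no gene changed in the diet comparison under vehicle, 0 of 20006 were called. The simulated noise was independent between genes, while genes in these libraries vary together, so these figures may not carry over to the real data. Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, library weights, the replicate number as a block, the samples in the fit, the threshold, and leaving out each library in turn. As deposited, the median log2 fold change of all genes was 0.10 for diet under vehicle and 0.12 for diet under 1,25D; quantile normalization moved these to 0 and 0.01.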

Results

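Male mice without Cyp27b1, the enzyme that makes the hormone 1,25D from its precursor, were raised from weaning at 3 weeks on diets deficient in vitamin D. The normal diet held 0.47% calcium and 0.3% phosphorus. The rescue diet, used to keep mineral supply up when the hormone is missing, held 2% calcium, 1.25% phosphorus and 20% lactose. When 8 weeks old, mice received an injection of vehicle or of 2 ng 1,25D per g of body weight, and RNA from the duodenum, the intestinal segment next to the stomach, was sequenced 6 h later. Each of the 4 groups had 6 libraries. The labels give 12 mice per diet, and their number of injected mice per group differs from the number of libraries. They do not tie libraries to animals, so p-values measure the spread between these libraries.

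Summed RPKM ranged from 541395 to 697913 per library. The absolute depth is unknown, and relative depth ran from 0.605 to 1.675 around a geometric mean of 1. Correlations of log2 values between libraries ran from 0.867 to 0.981, and no pair of libraries was identical. The first principal component held 31.2% of the variance.

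Cyp27b1 itself lay at or below 0.452 RPKM in all 24 libraries and was listed at 0 in normal vehicle replicate 4 and normal 1,25D replicate 4. Its mean was 0.228 ± 0.153 RPKM in normal vehicle, 0.0797 ± 0.0607 in normal 1,25D, 0.206 ± 0.104 in rescue vehicle and 0.179 ± 0.113 in rescue 1,25D (SD, n = 6 each). No wild type is analysed here, and the part of the gene that was removed is not given, so these values describe the libraries without checking their labels. They lie below 1.17 RPKM, the median of the receptor genes used as background.

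The first comparison asks which duodenal genes respond to 1,25D on the normal diet. Cyp24a1, the enzyme that starts the breakdown of 1,25D, rose 563-fold (log2 fold change 9.14, SE 0.44), from 1.08 ± 1.47 to 724 ± 219 RPKM (SD, n = 6 each). 3 calcium handling genes rose too. S100g, the cytosolic calcium carrier calbindin, rose 14.3-fold (log2 3.83, SE 0.60) from 263 ± 279 to 2141 ± 453 RPKM. The fold compares means of log values, which the low 13.63 RPKM of normal vehicle replicate 1 affects. Leaving out 1 library moved the log2 change of S100g between 3.16 and 4.31. Trpv6, the calcium channel of the brush border, rose 8.74-fold (log2 3.13, SE 0.45) from 0.281 to 7.18 RPKM. Atp2b1, the calcium pump of the basolateral membrane, rose 3.96-fold (log2 1.99, SE 0.22) from 78.5 to 299 RPKM. Adjusted p was 5.72e-13 for Cyp24a1, 0.000567 for S100g, 0.00023 for Trpv6 and 8.65e-06 for Atp2b1. For each the 6 treated libraries lay above all 6 vehicle libraries. Vdr, the receptor of 1,25D, did not pass the test (log2 0.14, SE 0.25, adjusted p = 0.958; -0.04 after quantile normalization), at 62.9 ± 22.6 RPKM under vehicle and 67.7 ± 19.3 RPKM after 1,25D.

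In all, 368 of 20006 genes were called, 357 higher and 11 lower, and 137 of them (133 higher, 4 lower) changed by 2-fold or more. The median log2 fold change of the called genes was 0.84, and 2393 genes had an unadjusted p under 0.05 where 1000 are due by chance. The split between higher and lower depended on scaling: quantile normalization gave 231 higher and 93 lower, and median-of-ratios scaling 227 and 122, each sharing 228 genes with the count above. Leaving out both normal vehicle replicate 6 and rescue 1,25D replicate 4, a choice made after the data were seen, gave 281 higher and 115 lower. The count was 233 without normal vehicle replicate 1 and 200, 228 and 236 without normal 1,25D replicates 3, 4 and 6. An exocrine pancreas covariate gave 134.

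**Figure D1:**
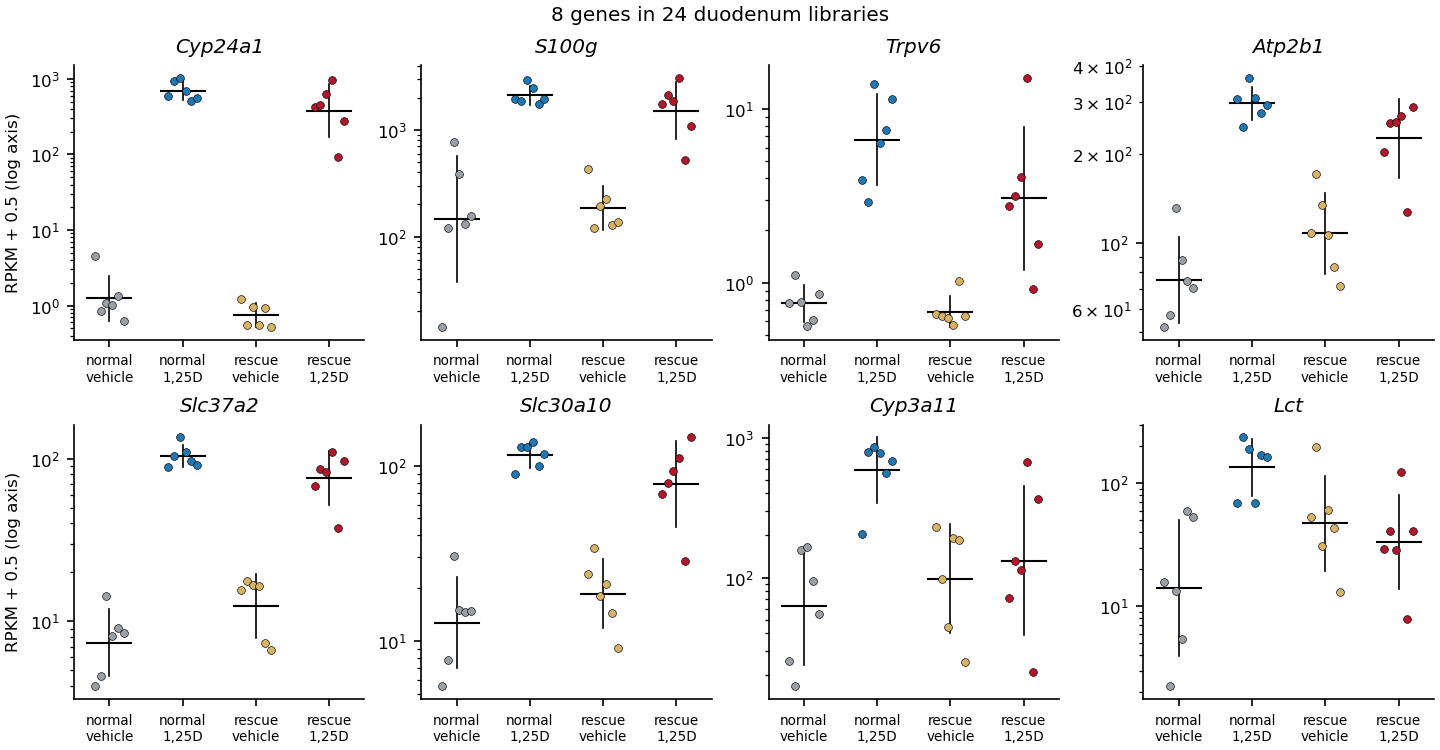
Each point is 1 library, on a log axis of RPKM + 0.5, for 8 genes in the 4 groups of 6; the horizontal bar is the mean and the vertical line 1 SD of the log values. Cyp24a1, S100g and Slc37a2 lie higher in all treated libraries than in any vehicle library of the same diet, while Lct and Cyp3a11 separate on the normal diet and overlap on the rescue diet.

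Of 19 measured members of the list of textbook 1,25D targets, 9 rose and 10 were not called (median log2 0.36; camera adjusted p = 1.46e-14, and adjusted p = 0.0125 with an estimated correlation); 9 rose when adjusted over the list alone. Besides the genes above they include Slc37a2, a sugar phosphate exchanger, up 13.9-fold (log2 3.80, SE 0.30, adjusted p = 1.83e-08). They also include Slc30a10, a manganese exporter, up 9.01-fold (log2 3.17, SE 0.36), and Cldn2, a claudin that forms cation pores in tight junctions, up 2.67-fold (log2 1.42, SE 0.25). Members such as Slc30a10 and Slc37a2 became known as targets through studies of the intestine that can include these libraries, so the list is not independent evidence of its direction. In the list of intestinal calcium transport, 4 of 13 members rose (6 adjusted over the list alone; adjusted p = 0.0608 with an estimated correlation).

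Phosphate and metal transport genes were the next group. Of 12 phosphate genes 4 rose (5 adjusted over the list alone), among them the intestinal alkaline phosphatases Akp3 (6.19-fold, log2 2.63, SE 0.48) and Alpi (3.07-fold, log2 1.62, SE 0.32) and the scaffold protein Slc9a3r1 (2.29-fold, log2 1.2, SE 0.22). The other was Slc37a2, given above, so no member of the phosphate transporter families Slc34 and Slc20 was called. The list had adjusted p = 0.0608 with an estimated correlation. Of 16 zinc and manganese transport genes 6 rose (9 adjusted over the list alone), led after Slc30a10 by the zinc exporters Slc30a2 (4.29-fold, log2 2.10, SE 0.31) and Slc30a1 (2.41-fold, log2 1.27, SE 0.15). That list had adjusted p = 0.0608 with an estimated correlation. Of 19 iron and copper genes 3 rose (8 higher and 1 lower adjusted over the list alone), including Heph, the ferroxidase that works with basolateral iron export (2.49-fold, log2 1.31, SE 0.28), and the iron regulatory protein Ireb2 (1.73-fold, log2 0.79, SE 0.18). That list had adjusted p = 0.24 with an estimated correlation.

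The enzymes and pumps that clear foreign compounds had the highest median of all 36 lists. Of 33 measured, 9 rose (25 adjusted over the list alone) with a median log2 of 0.95; camera gave adjusted p = 1.22e-20, and the list had adjusted p = 0.062 with an estimated correlation. Cyp2b10 rose 12.2-fold (log2 3.61, SE 0.57), Cyp3a11 9.46-fold (log2 3.24, SE 0.70), the glutathione transferase Gstm3 5.18-fold (log2 2.37, SE 0.38) and the efflux pump Abcb1a 2.10-fold (log2 1.07, SE 0.23). Cyp3a16, outside the list and a close copy of Cyp3a11, rose 9.03-fold (log2 3.18, SE 0.77). Of 25 carbohydrate genes 5 rose (11 adjusted over the list alone; median 0.50), among them lactase, Lct (9.53-fold, log2 3.25, SE 0.70), and the sodium-glucose cotransporter family member Slc5a4a (7.78-fold, log2 2.96, SE 0.42). Trehalase, Treh rose 2.96-fold (log2 1.57, SE 0.41), and the gluconeogenic enzyme Fbp1 3.18-fold (log2 1.67, SE 0.31). Of 33 lipid genes 2 rose (18 adjusted over the list alone; median 0.60), the fatty acid carrier Fabp2 (3.24-fold, log2 1.7, SE 0.37) and the peroxisomal enzyme Ehhadh (1.91-fold, log2 0.94, SE 0.22). Of 21 peptide and amino acid genes 3 rose (7 adjusted over the list alone; median 0.44), including the protease Mep1a (2.74-fold, log2 1.46, SE 0.24) and the dipeptidase Pepd (2.03-fold, log2 1.02, SE 0.22). These 3 lists each had adjusted p = 0.19 with an estimated correlation. A score of 19 general epithelial genes differed by 0.233, which did not pass after adjustment (exact permutation p = 0.0238, adjusted p = 0.225).

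Smaller numbers of genes rose elsewhere. Of 24 sterol synthesis genes 2 rose (3 adjusted over the list alone) with all 24 above 0. The list had adjusted p = 0.267 with an estimated correlation. Of 18 clock genes 3 rose (5 higher and 1 lower adjusted over the list alone), among them Per2 (2.00-fold, log2 1.00, SE 0.26) and Tef (1.60-fold, log2 0.68, SE 0.16). The list had adjusted p = 0.133 with an estimated correlation. With the values as deposited 11 genes fell, and more fell with the other scalings given above. Among the 11, Apol10a, of the apolipoprotein L family, fell 3.28-fold (log2 -1.71, SE 0.38), and the water channel Aqp4 2.08-fold (log2 -1.06, SE 0.23). The muscarinic acetylcholine receptor Chrm3 fell 1.66-fold (log2 -0.73, SE 0.14) and the sulfhydryl oxidase Qsox2 1.59-fold (log2 -0.67, SE 0.15). The calls of Treh and of Ccdc141 (log2 -0.57) held in 9 and 12 of the 24 fits that left out 1 library.

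The exocrine pancreas list had a median log2 of -3.39 after 1,25D (0 of 25 called, 23 lower adjusted over the list alone; camera adjusted p = 1.47e-21, adjusted p = 0.169 with an estimated correlation). Trypsinogen, Prss1, went from 107 ± 107 to 10.1 ± 18.6 RPKM (log2 -3.92, SE 1.11, adjusted p = 0.0709). Pancreas genes made up 17.66% of the summed RPKM in normal vehicle replicate 6 and 0.01% in normal 1,25D replicate 6. Smooth muscle genes had a median of -0.42 (0 of 16 called; adjusted p = 0.426 with an estimated correlation), Paneth cell genes -0.53 (0 of 23 called, 2 lower adjusted over the list alone; 0.19), and crypt stem cell genes -0.43 (0 of 13 called, 2 lower adjusted over the list alone; 0.21). The stem cell receptor Lgr5 was at 2.02 ± 0.769 RPKM under vehicle and 0.970 ± 0.149 RPKM after 1,25D (log2 -0.73, SE 0.22, adjusted p = 0.0903).

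The second comparison asks the same on the rescue diet. Cyp24a1 rose 512-fold (log2 9.0, SE 0.44, adjusted p = 8.13e-13), from 0.284 ± 0.285 to 473 ± 299 RPKM (SD, n = 6 each). S100g rose 8.21-fold (log2 3.04, SE 0.60, adjusted p = 0.0336) from 205 to 1740 RPKM. Trpv6 rose 4.50-fold (log2 2.17, SE 0.45, adjusted p = 0.0484) from 0.196 to 4.13 RPKM. Atp2b1 rose 2.10-fold (log2 1.07, SE 0.22, adjusted p = 0.0484) from 112 to 234 RPKM. Slc37a2 rose 6.10-fold (log2 2.61, SE 0.30), Slc30a10 4.23-fold (log2 2.08, SE 0.36) and Slc30a1 1.90-fold (log2 0.93, SE 0.15). Vdr again did not pass the test (log2 -0.26, SE 0.25, adjusted p = 0.879).

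In all 29 genes were called, 28 higher and 1 lower, 16 of them by 2-fold or more, and 966 genes had an unadjusted p under 0.05 where 1000 are due by chance. Quantile normalization gave 45 higher and 7 lower, and array weights 66 and 24. Others that rose were Pdlim2, a PDZ and LIM domain protein (5.52-fold, log2 2.46, SE 0.32), Lrrc26, a potassium channel subunit (2.84-fold, log2 1.51, SE 0.28). So did Pgap1, which trims the lipid anchor of surface proteins (2.56-fold, log2 1.36, SE 0.16), Ttc22 (2.45-fold, log2 1.29, SE 0.24) and Ccdc134 (2.31-fold, log2 1.21, SE 0.20). Maoa, a monoamine oxidase, was the 1 gene that fell (1.71-fold, log2 -0.77, SE 0.16, adjusted p = 0.0484). Of the 24 fits that left out 1 library, 24 kept the calls of Cyp24a1, Slc37a2, Slc30a10, Pdlim2 and Pgap1, 15 that of S100g, 5 that of Trpv6 and 4 those of Atp2b1 and Maoa. The count moved to 48 without normal vehicle replicate 6, to 19 without normal 1,25D replicates 5 or 6 or rescue 1,25D replicate 1. It was 16 without rescue vehicle replicate 1 or rescue 1,25D replicate 4, 15 without rescue vehicle replicates 4 or 6 or rescue 1,25D replicate 2, 14 without rescue vehicle replicate 5 or rescue 1,25D replicate 3, and 12 without rescue vehicle replicate 3.

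The lists of textbook targets (6 of 19 higher, 7 adjusted over the list alone; median 0.32) and calcium transport (3 of 13 higher, 5 adjusted over the list alone; median 0.33) each kept adjusted p = 0.0284 with an estimated correlation. Of 16 zinc and manganese genes 2 rose (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). No gene of the xenobiotic, lipid, carbohydrate or peptide lists was called by limma. Their medians were -0.18, -0.30, -0.33 and -0.21; the xenobiotic list had a mean of 0.01, against the sign of its median, and adjusted p = 0.679 with an estimated correlation, the other 3 lists 0.376. Over the list alone 1 xenobiotic gene was higher and 2 peptide genes were lower. Among them Cyp2b10 had a log2 fold change of 1.53 (SE 0.57, adjusted p = 0.878) and Gstm3 of 1.59 (SE 0.38, 0.134). Fabp1 had one of -0.76 (SE 0.30, 0.878), Sis, the sucrase of the brush border, of -0.78 (SE 0.28, 0.817) and the proline transporter Slc6a20a of -1.31 (SE 0.31, 0.121). Ion and water transport genes had a median of -0.34 (0 of 25 called, 1 lower adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). In this list the water and glycerol channel Aqp3 went from 1.91 ± 1.07 to 0.351 ± 0.268 RPKM (log2 -1.41, SE 0.36, adjusted p = 0.221). The exocrine pancreas list had a median of -0.29 here (0 of 25 called; 0.902).

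Between the diets, the genes called for 1,25D overlapped. All 28 genes higher on the rescue diet were also among the 357 higher on the normal diet, against 0.5 for independent lists (Fisher's exact p = 3.79e-50). The 2 comparisons set different libraries against each other, but 1 fit gave both the same estimate of spread for each gene. The lists are therefore not independent, and neither the 0.5 nor the Fisher p allows for that. Across the 369 genes called on either diet, Pearson's r of the fold changes was 0.74 and Spearman's rho 0.42; genes are not independent replicates. Of the 368 genes called on the normal diet, 276 (75%) had the same sign on the rescue diet, against 56.1% of all genes tested, and 140 of these had an unadjusted p under 0.05 there. Their median log2 fold change was 0.84 on the normal and 0.24 on the rescue diet; they were selected on the normal diet, which by itself makes the second median smaller. Across all genes r was 0.13. The overlap was 43 without normal vehicle replicate 6, 16 without rescue vehicle replicate 1, 15 without rescue vehicle replicates 4 or 6 or rescue 1,25D replicate 2, 14 without rescue vehicle replicate 5 or rescue 1,25D replicate 3, 13 without rescue 1,25D replicate 4 and 12 without rescue vehicle replicate 3.

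**Figure D2:**
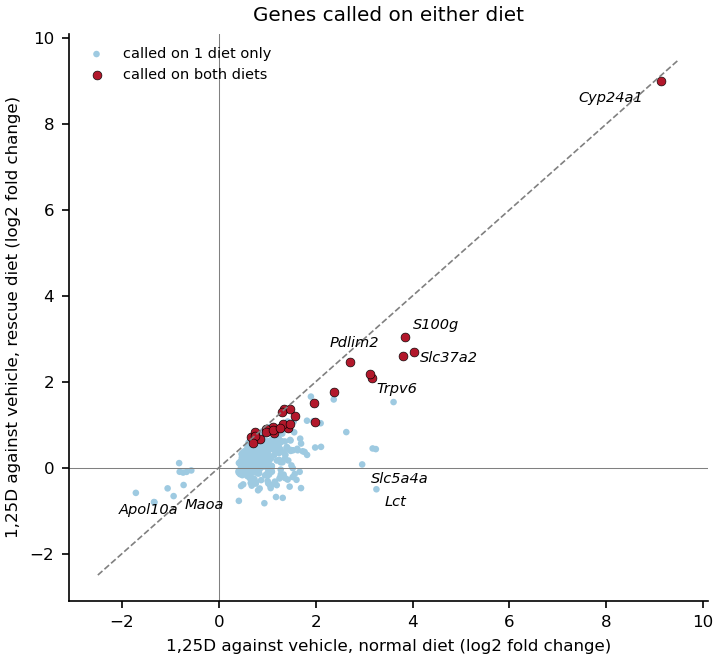
Each point is 1 of the 369 genes called on either diet, with its log2 fold change for 1,25D against vehicle on the normal diet (x) and on the rescue diet (y); red points are the 28 genes called on both diets, blue points those called on 1, and the dashed line marks equal change. Cyp24a1 lies near the line, S100g, Slc37a2 and Trpv6 lie below it, and Lct and Slc5a4a lie near 0 on the rescue diet.

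The third comparison asks whether the effect of 1,25D differed between the diets. For Cyp24a1 and the calcium handling genes no difference passed the test. The interaction was -0.14 on the log2 scale for Cyp24a1 (SE 0.62, adjusted p = 0.989), -0.80 for S100g (SE 0.85, 0.961), -0.96 for Trpv6 (SE 0.64, 0.904) and -0.92 for Atp2b1 (SE 0.32, 0.417). Upb1, an enzyme of pyrimidine breakdown, was the 1 gene that passed: it went from 3.90 to 9.5 RPKM with 1,25D on the normal diet and from 5.73 to 3.61 RPKM on the rescue diet (interaction log2 -1.86, SE 0.29, adjusted p = 0.024). Unadjusted p was under 0.05 for 1371 genes, and array weights gave 32 calls, 31 of them lower. With a smooth muscle or pancreas covariate the count was 0, and leaving out 1 library kept the call of Upb1 in 11 of 24 fits. The count was 17, 16 and 11 without rescue 1,25D replicate 4, rescue vehicle replicate 6 and rescue 1,25D replicate 6, 7 without normal vehicle replicate 5, and 5 without normal 1,25D replicate 1. It was 0 without any of normal vehicle replicates 1, 3 and 4, normal 1,25D replicates 4 to 6, rescue vehicle replicates 1 to 4 and rescue 1,25D replicates 1 to 3.

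The xenobiotic list had a median interaction of -1.08 (0 of 33 called, 19 lower adjusted over the list alone), the lipid list -0.89 (0 of 33, 18), the carbohydrate list -0.89 (0 of 25, 15) and the peptide list -0.57 (0 of 21, 9), each at adjusted p = 0.0817 with an estimated correlation. Slc5a4a had an interaction of -2.88 (SE 0.60, adjusted p = 0.133), the glucuronosyltransferase Ugt2b5 of -2.40 (SE 0.57, 0.187) and the apolipoprotein Apoa1 of -2.26 (SE 0.62, 0.261). Fabp2 had one of -2.17 (SE 0.53, 0.187), the aminopeptidase Enpep of -1.63 (SE 0.38, 0.187) and Abcb1a of -1.54 (SE 0.32, 0.133). The phosphate list had a median of -0.39 (4 of 12 lower adjusted over the list alone; 0.115 with an estimated correlation). Marker lists of other tissues and cell types lay on both sides. The median was 3.05 for exocrine pancreas (0 of 25 called; 0.304) and 0.49 for smooth muscle (0 of 16; 0.525). It was -0.97 for Brunner's glands and stomach (0 of 9; 0.525), -0.45 for T cells (0 of 15, 3 lower adjusted over the list alone; 0.132), -0.31 for enteroendocrine cells (0 of 20, 4 lower adjusted over the list alone; 0.304) and -0.27 for goblet cells (0 of 13; 0.203). No list passed with an estimated correlation, with which camera's 20 calls were lost. With fry 6 lists passed on the lower side, xenobiotic, carbohydrate, peptide and clock genes at adjusted p = 0.036 and lipid and ion and water transport genes at 0.0408.

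The fourth comparison asks how the rescue diet changes the duodenum under vehicle. limma called 0 of 20006 genes, with a smallest adjusted p of 0.101 and 1437 genes at an unadjusted p under 0.05 where 1000 are due by chance; leaving out normal vehicle replicate 4 gave 4. Cyp24a1 had a log2 fold change of -0.74 (SE 0.44, adjusted p = 0.742), S100g 0.32 (SE 0.60, 0.946), Trpv6 -0.16 (SE 0.45, 0.972), Atp2b1 0.52 (SE 0.22, 0.668) and Vdr 0.27 (SE 0.25, 0.859). Reg3a, an antimicrobial lectin, was at 15.2 ± 11.2 RPKM on the normal and 2.78 ± 2.14 RPKM on the rescue diet (log2 -2.11, SE 0.46, adjusted p = 0.226).

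Of the lists, 11 higher and 5 lower passed camera, and none passed with an estimated correlation (smallest adjusted p = 0.394). Carbohydrate genes had a median of 0.31 (4 of 25 higher adjusted over the list alone; adjusted p = 0.75 with an estimated correlation), led by Dak, a kinase of fructose breakdown (log2 0.54, SE 0.15, adjusted p = 0.475). Xenobiotic genes had a median of 0.43 (1 of 33 higher adjusted over the list alone; 0.75), led by Abcb1a (log2 0.86, SE 0.23, 0.475). Cell cycle genes had a median of 0.31 (0 of 26 called; 0.77), with the replication clamp Pcna at 0.60 (SE 0.19, adjusted p = 0.567). The Paneth cell list had a median of 0.02 and a mean of -0.27, and camera put it lower (1 of 23 lower adjusted over the list alone; 0.77 with an estimated correlation). The exocrine pancreas list had a median of -2.99 (0 of 25 called), and its score differed by -2.84, which did not pass after adjustment (exact permutation p = 0.0281, adjusted p = 0.225).

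The fifth comparison sets the diets against each other after 1,25D. Sepp1, the plasma selenium carrier selenoprotein P, fell 3.64-fold on the rescue diet (log2 -1.87, SE 0.32, adjusted p = 0.0417), from 497 ± 127 to 145 ± 85.5 RPKM (SD, n = 6 each), with 5 of 6 rescue libraries below all normal ones. Upb1 fell 2.56-fold (log2 -1.36, SE 0.21, adjusted p = 0.0152), from 9.5 ± 2.01 to 3.61 ± 1.55 RPKM, with 6 of 6 below. These were the 2 genes called, and 1676 had an unadjusted p under 0.05. The count depended on how libraries were weighted: array weights gave 1287 calls, 815 higher and 472 lower, and the smooth muscle score as a covariate gave 0. Of the 24 fits that left out 1 library, 11 kept the call of Sepp1 and 19 that of Upb1. Leaving out both normal vehicle replicate 6 and rescue 1,25D replicate 4, chosen after the data were seen, gave 57 calls, 34 of them lower. The count was 14, 7 and 5 without rescue 1,25D replicate 4, rescue 1,25D replicate 6 and normal vehicle replicate 6. It was 1 without normal vehicle replicate 4, normal 1,25D replicates 2 or 3, rescue vehicle replicates 3, 4 or 5, or rescue 1,25D replicates 2 or 5; and 0 without normal 1,25D replicates 4, 5 or 6 or rescue 1,25D replicates 1 or 3.

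After 1,25D, 7 lists were lower on the rescue diet and kept their call with an estimated correlation, with no member called over all genes. The medians were -0.63 for xenobiotic genes (16 of 33 lower adjusted over the list alone; adjusted p = 0.0364 with an estimated correlation), -0.53 for carbohydrate genes (12 of 25 lower and 1 higher; 0.0364), -0.51 for lipid genes (12 of 33 lower and 1 higher; 0.0361), -0.47 for ion and water transport (2 of 25; 0.0478). They were -0.40 for peptide genes (8 of 21; 0.0361), -0.35 for T cell genes (6 of 15; 0.0361) and -0.28 for clock genes (8 of 18 lower and 1 higher; 0.0361). With fry none of the 7 passed, with adjusted p from 0.0863 to 0.148. Members with small p were Enpep (log2 -1.28, SE 0.27, adjusted p = 0.142), Slc6a20a (-1.43, SE 0.31, 0.159), Apoa1 (-1.74, SE 0.44, 0.267), Slc5a4a (-1.71, SE 0.42, 0.267). Others were the gut peptide hormone Guca2b (-1.93, SE 0.49, 0.267), the retinaldehyde dehydrogenase Aldh1a1 (-0.77, SE 0.21, 0.332) and granzyme A, Gzma, of cytotoxic lymphocytes (-1.84, SE 0.44, 0.244). In the clock list, the transcription factor Arntl was higher in 6 of 6 rescue libraries than in any normal one (0.94, SE 0.24, 0.267), and Tef had a log2 fold change of -0.60 (SE 0.16, 0.332).

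Other lists differed in size without a call that held. Cell cycle genes had a median of 0.44 with all 26 above 0 (1 higher adjusted over the list alone; adjusted p = 0.25 with an estimated correlation); the spindle checkpoint kinase Bub1 had a log2 fold change of 0.79 (SE 0.22, adjusted p = 0.354). Smooth muscle genes had a median of 0.51 with all 16 above 0 (0 called; 0.483), and the smooth muscle score differed by 0.529 (exact permutation p = 0.158, adjusted p = 0.61). The exocrine pancreas list had a median of 0.23 (0 of 25 called; 0.84). The log2 fold change was -0.88 for Cyp24a1 (SE 0.44, adjusted p = 0.609), -0.47 for S100g (SE 0.60, 0.826), -1.12 for Trpv6 (SE 0.45, 0.52), -0.40 for Atp2b1 (SE 0.22, 0.668) and -0.14 for Vdr (SE 0.25, 0.869).

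**Figure D3:**
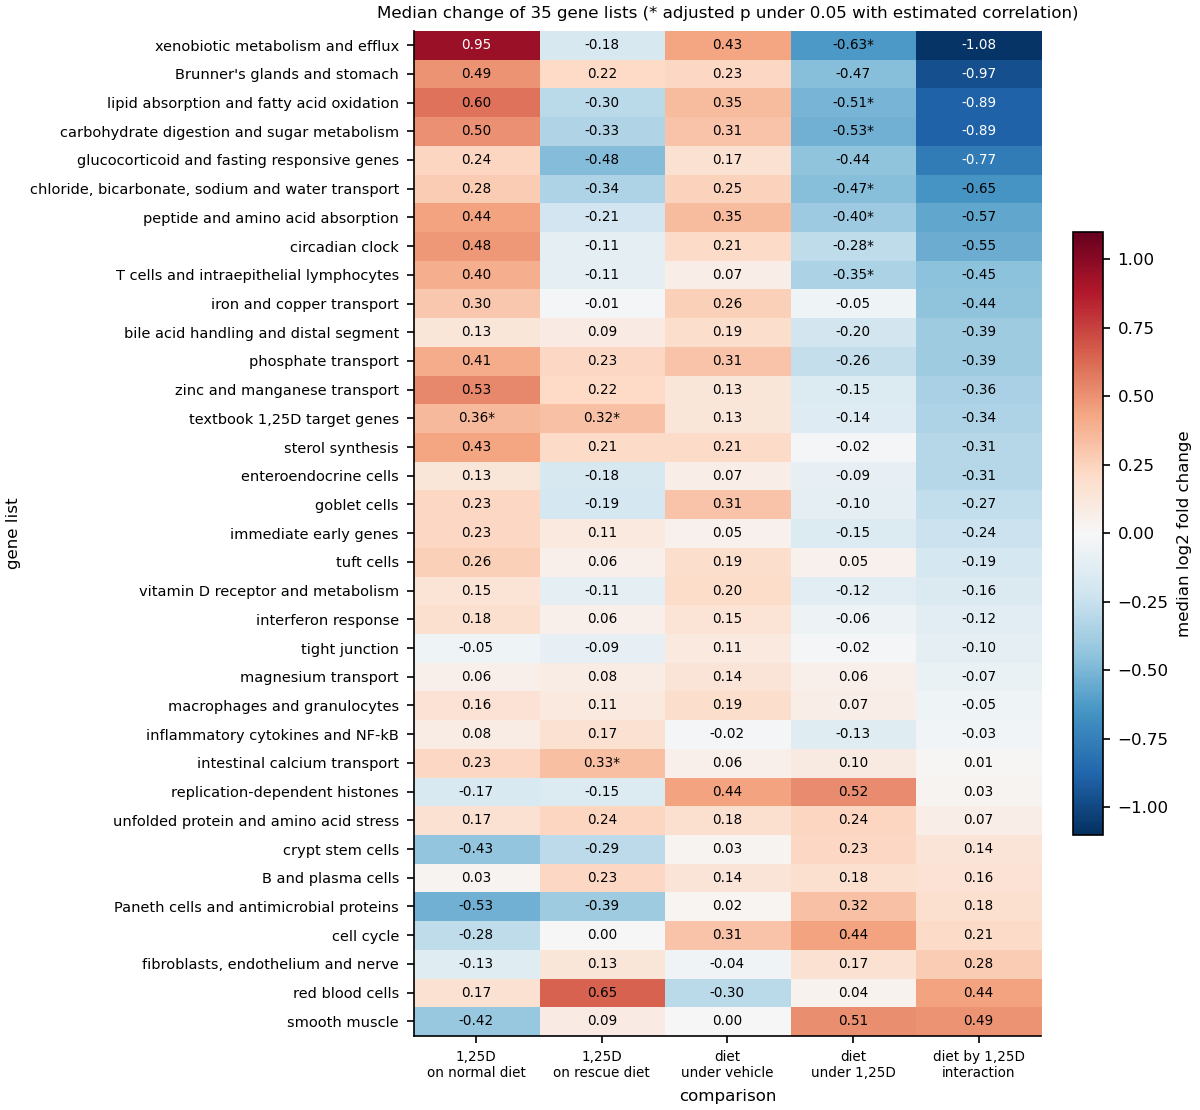
Each cell is the median log2 fold change of 1 gene list (y) in 1 of the 5 comparisons (x), on a color scale from blue (lower) to red (higher); the exocrine pancreas list, with medians down to -3.39, is left out, and an asterisk marks adjusted p under 0.05 with an estimated correlation. The xenobiotic, lipid, carbohydrate and peptide lists are positive for 1,25D on the normal diet and negative on the rescue diet, where the xenobiotic mean is 0.01.

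**Figure D4:**
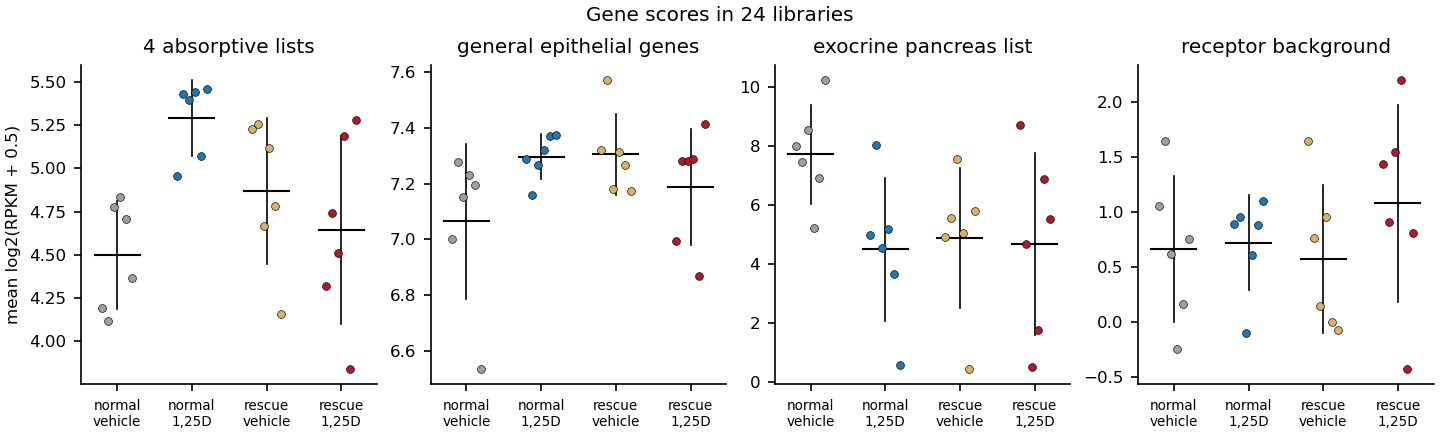
Each point is the mean log2(RPKM + 0.5) of 1 library over the 112 genes of 4 absorptive lists, 19 general epithelial genes, the exocrine pancreas list, and the receptor genes used as background, by group of 6; the horizontal bar is the mean and the vertical line 1 SD. The pancreas score reaches 10.2 in normal vehicle replicate 6 and spans several log2 units within each group.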

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

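Tests of pancreas carry-over, of a pancreas response, of villus and crypt shares and of the 3 library scores were chosen after the results were seen; those of background and of the epithelial median use scores chosen after the data were seen, with bounds written before their results, and the sample splits were set beforehand. An outlying library was sought in each group of 6, where chance alone picks out about 1 group in 20: 12 of 179 groups for genes met the criterion (9 by chance) and 5 of 28 for library measures.

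Single libraries far from the other 5 of their group were as follows, in RPKM with the range of the others. In normal 1,25D replicate 1, Cyp3a11 was at 203 (555 to 864), Treh at 31.2 (47.6 to 61), Pepd at 40.1 (49.5 to 55) and Sepp1 at 244 (518 to 588). In normal vehicle replicate 6, Slc30a1 was at 10.4 (15.2 to 17.4) and Junb at 5.71 (9.73 to 12). In rescue vehicle replicate 4, Gstm3 was at 19.4 (11.3 to 12.5), in replicate 5 Trpv6 at 0.529 (0.074 to 0.16), and in replicate 6 Fabp2 at 258 (622 to 1000) and Sis at 296 (766 to 952). In rescue 1,25D replicate 6, Abcb1a was at 58.4 (21.9 to 29.2) and Bub1 at 5.56 (9.28 to 12.4). Among library measures, rescue 1,25D replicate 5 had 2705 symbols at 0 (987 to 1550), rescue vehicle replicate 5 a pancreas score of 0.432 (4.909 to 7.555), normal vehicle replicate 1 a muscle score of 5.8 (4.106 to 4.52), and normal vehicle replicate 6 and rescue vehicle replicate 2 epithelium scores of 6.532 (6.999 to 7.277) and 7.573 (7.174 to 7.322).

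The effects of 1,25D differed between the diets for Upb1 (log2 -1.86). By camera with a preset correlation, 20 lists differed, none with an estimated correlation. Their median interactions were -1.08 for xenobiotic, -0.89 for carbohydrate and for lipid, -0.77 for glucocorticoid and fasting, -0.65 for ion and water transport, -0.57 for peptide and -0.55 for clock genes. They were -0.45 for T cells, -0.44 for iron and copper, -0.39 for phosphate, -0.36 for zinc and manganese, -0.34 for textbook targets, -0.31 for sterol synthesis and for enteroendocrine cells, -0.27 for goblet cells and -0.24 for immediate early genes. They were 3.05 for exocrine pancreas, 0.49 for smooth muscle, 0.28 for fibroblasts, endothelium and nerve, and 0.18 for Paneth cells.

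Exocrine pancreas genes differed by several log2 units between libraries, with Cela1 at a mean of 484.7 and Cpa1 at 486.3 RPKM in normal vehicle and 70.94 and 79.56 in normal 1,25D. None of the 25 genes is in another list. Within groups they varied together (median pairwise correlation 0.98), so pancreatic tissue carried along with some duodenum pieces may be the source. Over the 4 groups the score had a permutation p of 0.103, which does not decide whether 1,25D or diet also acts on these genes, and that stays open.

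The 112 genes of the xenobiotic, lipid, carbohydrate and peptide lists had a median of 0.62 for 1,25D on the normal diet and -0.24 on the rescue diet; they were picked for these opposite signs, and none of the 4 lists passed the interaction test with an estimated correlation (adjusted p = 0.0817 each). Uneven background reads are argued against, since 1.05 of the median interaction was left with the background score as a covariate. The median interaction of -0.93 became -0.76 with the smooth muscle score as a covariate and -0.83 with the exocrine pancreas score. A different share of epithelium stays open: 19 general epithelial genes had a median interaction of -0.23 (95% interval -0.56 to -0.07, which spans the bounds set), and over 3 permutation tests the interaction of the library score was -0.35 for these genes (SE 0.16, p = 0.0269, adjusted p = 0.0269), -1.02 for the absorptive genes (SE 0.32, p = 0.00421, adjusted p = 0.0126) and -0.67 for the difference (SE 0.27, p = 0.0254, adjusted p = 0.0269), the last 2 favored by the way the lists were picked. These permutations shuffled the diets within each injection. Their p-values therefore assume no diet effect under either injection, which is more than an equal effect of 1,25D on both diets. A shift between villus and crypt cells cannot be told apart from a different share of epithelium, since cell cycle genes had a median interaction of 0.21, between the bounds set. Their 95% interval of 0.02 to 0.24 also resamples genes, which correlate at 0.67 in this list, so it cannot decide the question. Camera with an estimated correlation gave this list adjusted p = 0.693 for the interaction. A different action of 1,25D on these genes by diet may also contribute, and the difference of -0.67 does not settle it, given how the lists were picked. Fkbp5, of the glucocorticoid and fasting list (median interaction -0.77), also varied within groups. In rescue 1,25D, replicates 4 and 6 had the highest Fkbp5 (73.05 and 148.4 RPKM), Cyp3a11 (669.9 and 361.8) and absorptive score (5.185 and 5.28). In rescue vehicle, replicate 2 had the lowest Fkbp5 (10.88 RPKM) and the highest absorptive score (5.256). Whether a fasting or glucocorticoid state plays a part was not tested.

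In 100 splits of the libraries, real one included, the 368 genes for 1,25D on the normal diet were reached by 1 split (highest other 1), so chance alone is an unlikely source of this count. The other splits mix treated and vehicle libraries, so they speak to the count and not to each of the 368 genes. The 29 on the rescue diet were reached by 6 splits, so chance is not excluded for the count; the highest other, 2534, parts libraries with mean background scores of 0.22 and 1.42 and points to a structure of the samples. For diet under vehicle 100 splits reached 0 (highest other 1). For diet under 1,25D 2 splits reached 2 (highest other 2), and for the interaction 3 reached 1 (highest other 3), each a share under 0.05.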

How the results depend on the processing

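The smooth muscle, background and pancreas covariates, testing each deposited entry by itself and leaving out 2 libraries together were chosen after the results were seen. Of 112 gene results 55 were called, and 25 of these kept their call in all 14 alternative fits made for single genes and with every left-out library. The stricter thresholds and the fit of each deposited entry were not among these 14. Under the thresholds some of the 25 fail, such as Aqp4 on the normal diet (adjusted p = 0.0137 by limma) at 0.01. Where a count moved the cause was not tested, except that fewer genes or samples enter some alternatives. For 1,25D on the normal diet, 368 became 134 with the pancreas covariate, 149 at adjusted p under 0.01 and 137 at 2-fold. On the rescue diet, 29 became 52 with quantile normalization, 48 with median-of-ratios scaling, 90 with array weights, 11 at 0.01, 16 at 2-fold and 11 with only the groups compared. Diet under vehicle gave 0 in 17 alternatives. For diet under 1,25D, 2 became 1 with no filter, 4 with either scaling, 1287 with array weights (815 higher, 472 lower) and 1 with the block. It became 0 with the muscle covariate, 57 with 2 libraries left out, 1 with each deposited entry, 0 at 0.01 and 0 with only the groups compared. The interaction gave 2 with quantile normalization, 0 with median-of-ratios scaling, 32 with array weights, 0 with the muscle or pancreas covariate, 11 with 2 libraries left out and 0 at 0.01. The overlap of 28 became 56 with array weights, 18 with the background covariate, 11 at 0.01 and 16 at 2-fold. Leaving out 1 library gave 200 to 453 for the normal diet and 12 to 48 for the rescue diet. It gave 0 to 4 and 0 to 14 for diet under vehicle and under 1,25D, 0 to 17 for the interaction and 12 to 43 for the overlap; the libraries are named beside each result. Results that reversed were never called: the interaction of Cyp24a1 at 0.47 with pseudocount 0.1, 0.24 with array weights, 0.13 with the pancreas covariate, and 0.06, 0.01 and 0.27 without normal vehicle replicate 6, rescue vehicle replicate 1 and rescue 1,25D replicate 5 (range -0.51 to 0.27 over single left-out libraries). Vdr on the normal diet was at -0.04 with quantile normalization and with array weights, -0.01 with the muscle and the pancreas covariate and -0.01 without normal vehicle replicate 1; for diet under 1,25D it was at 0.05 with the muscle covariate. S100g for diet under vehicle was at -0.35 without normal vehicle replicate 1 (range -0.35 to 0.80). With fry 13, 2, 0, 0 and 6 lists passed in the 5 comparisons (1,25D on the normal and the rescue diet, diet under vehicle and under 1,25D, interaction). Replicate numbers did not pair libraries: 6 of 36 correlated best with their own number. Relative depth was estimated and absolute depth is not known, so no limit on low genes can be given from read counts. The 1338 receptor genes tested had a median of 1.17 RPKM over libraries and genes, above the 0.5 RPKM of the filter. Values near or below this median may hold background reads. Examples are Cyp27b1, Trpv6 under vehicle, Aqp3 after 1,25D on the rescue diet, and Lgr5 and Ccdc141 after 1,25D on the normal diet.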

Other observations

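The list tests in this part were planned, while the tests in the last paragraph were chosen after the result was seen. Among cell type markers, T cell and intraepithelial lymphocyte genes had a median log2 of 0.40 for 1,25D on the normal diet (0 of 15 called by limma, 1 higher adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). For the diet after 1,25D, Cd3g, a T cell receptor subunit, was at -1.2 (SE 0.32, adjusted p = 0.326). Goblet cell genes had medians of 0.23 on the normal diet (0 of 13 called; adjusted p = 0.558 with an estimated correlation) and -0.19 on the rescue diet (0 of 13; 0.376). Enteroendocrine genes had medians of 0.13 (0 of 20, 2 higher adjusted over the list alone; 0.558) and -0.18 (0 of 20; 0.397), tuft cell genes 0.26 (0 of 9; 0.38) and 0.06 (0 of 9; 0.902), and genes of Brunner's glands and stomach 0.49 (0 of 9; 0.426) and 0.22 (0 of 9; 0.939). The tuft list had a mean of 0 on the rescue diet and the Brunner list a mean of 0.06, each with the test on the lower side. Macrophage genes had medians of 0.16 and 0.11 (0 of 18 each), fibroblast, endothelium and nerve genes -0.13 (0 of 18; 0.53) and 0.13 (0 of 18; 0.869), and red blood cell genes 0.17 (0 of 6; 0.892) and 0.65 (0 of 6; 0.397). B cell genes had a median of 0.03 on the normal diet, with the test on the lower side (0 of 8 called, 1 higher adjusted over the list alone; 0.951).

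Junb, an immediate early transcription factor, rose 2.04-fold with 1,25D on the normal diet (log2 1.03, SE 0.24, adjusted p = 0.0189), the 1 of 20 immediate early genes called (3 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation). Ifi27l2b, an interferon-induced gene, rose 3.53-fold (log2 1.82, SE 0.33, adjusted p = 0.00247), 1 of 32 interferon response genes (1 adjusted over the list alone; 0.571). Inflammatory genes had a median of 0.08 with the test on the lower side (0 of 18 called; 0.904), and unfolded protein response genes 0.17 (0 of 21; 0.558). Glucocorticoid and fasting responsive genes had medians of 0.24 on the normal diet (0 of 16; 0.99) and -0.48 on the rescue diet (0 of 16; 0.397). Replication-dependent histones had a median of -0.17 with all 21 negative (0 of 21 called; 0.493) on the normal diet. The magnesium list had 2 of 9 members higher on the normal diet (3 higher and 1 lower adjusted over the list alone, 0.47 with an estimated correlation). The bile acid list had 1 of 9, the protease Mep1a, which is also in the peptide list (1 adjusted over the list alone, 0.571). The vitamin D receptor and metabolism list had 1 of 11, Cyp24a1 (2 adjusted over the list alone, 0.19). The tight junction list had a median of -0.05 and a mean of 0.13 (2 of 18 higher, 3 adjusted over the list alone; 0.892).

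The first principal component of all genes tested held 31.2% of the variance. Computed without the receptor genes, the first component held 22.3% of the variance. A permutation test of the latter component over the 4 groups gave p = 0.519, which leaves a diet or 1,25D part open. The latter component correlated with the background score over 24 libraries (r = 0.96, rho = 0.93, permutation p = 0.00001 for each, the smallest these permutations can give). Adjusted p was 0.00002 over 2 relations, and r was 0.94 without the 2 farthest libraries. Reads spread over genes that the duodenum does not use may therefore set this component. Relative depth had r = -0.42 with it (permutation p = 0.0423) and rho = -0.34 (permutation p = 0.106), a weaker relation than that of the background score. Without the 2 libraries farthest in depth r was -0.15. These were the shallowest, rescue 1,25D replicate 4 (0.605) and rescue vehicle replicate 1 (0.635). Leaving out the extremes of depth weakens a relation with depth by itself, so this does not decide whether depth plays a part.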
